A study of Camellia sinensis with 2 samples.

How the data were processed

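Single-cell RNA sequencing was done on protoplasts, which are cells freed from their walls by enzymes, from leaf blades of Camellia sinensis var. sinensis, the tea plant, cultivar Shuchazao. One library came from the first leaf of the tender shoot, called young in the labels, and 1 from the third leaf, called mature. The trees were 6 years old. The blades were digested for 4 hours at 25 °C with cellulase, macerozyme and snailase, and the suspension passed through a 40 µm mesh. Per the labels' protocols, the libraries were made with the 10x Genomics 3' v3 chemistry, which tags each captured transcript with a molecular identifier (UMI) and a barcode for its droplet.

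The deposited matrices hold raw UMI counts per gene and barcode, written by Cell Ranger 5.0.1 per the file headers. The submitters' processing notes also name bcl2fastq 2.20 and Seurat 3.1.1. The genome build, the gene annotation and the rule that kept barcodes are not given in the sources used here. The lists of genes and barcodes deposited with each matrix give names in matrix order and no measurements. Both libraries list the same 50525 gene IDs, and the name column repeats the ID. The reference table used here (RefSeq genes of another tea assembly, ASM5576180v1) matched 0 of these IDs. Gene names, positions and pathways were therefore not used, and the marker and pathway lists fixed beforehand (mesophyll, epidermis, guard cell lineage, phloem, xylem, procambium, proliferating cells, trichomes, catechin, galloylation, caffeine, theanine, photosynthesis, ribosome, stress, terpene and lignin genes) could not be applied. Clusters carry numbers, not cell type names. The 4 IDs named for the leaf comparison are those with the highest and lowest ratios, 2 in each direction, among genes with at least 50 CPM in the higher library. For a cluster, the leading ID is the gene with the highest level relative to all other barcodes among genes found in at least 25% of its barcodes in both libraries.

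Barcodes with at least 500 genes and 1000 UMIs were kept, which removed 1629 of the 10285 young-leaf barcodes and 594 of the 8110 mature-leaf barcodes. Counts were summed over the kept barcodes of each library and scaled to 1000000 UMIs (CPM). Each group has 1 library, and cells are not replicates, so no test between the leaves is possible and no p-value is given. Genes were counted by a rule of size: a CPM ratio of at least 2 and at least 20 CPM in the higher library. Poisson intervals of levels, conditional exact intervals of ratios and Clopper-Pearson intervals of shares are at 95% and cover counting error only. The rule was tested on simulated data for this comparison over all 50525 genes. It called 100% of 100 genes changed 3-fold and 0% of 100 genes changed 1.5-fold. The changed genes were drawn from those with at least 2 times 20 CPM in the young leaf, with counting error as the only noise. A cut at a ratio of 2 was then almost bound to give these values. Genes near 20 CPM, the rule inside clusters and replicate spread were not covered.

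Clusters were made with Seurat 5.3.0 in R 4.3.3 after log normalization, with 2000 variable genes, reciprocal PCA integration of the 2 libraries, 30 components and Louvain resolution 0.5. They are numbered by size. Clusters with at least 100 barcodes in each library were compared between the leaves on summed counts. To compare genes per barcode at one depth, every barcode was thinned to 1259 UMIs, the 10th percentile, and shallower barcodes were left out. Doublets were scored with scrublet in scanpy 1.11.5. Its own threshold marked 0 barcodes in each library, so the caller is taken not to have worked, and doublets stayed in.

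The design, the named-gene rule and most alternatives were fixed before the data were examined. Alternatives were TMM scaling (edgeR 4.0.16), median-of-ratios scaling (DESeq2 1.42.0), lower minimum levels, equal weight per barcode, thinning, other cluster resolutions (0.3 and 1.0), 15 components and no integration. Choices made after seeing the data were leaving out the 5% of barcodes with the highest doublet scores in each library, leaving out clusters held by 1 library or clusters not compared, all deposited barcodes as a source of gene counts, the number of genes per barcode at one depth, thinning to 3000 UMIs, and a clustering whose variable genes exclude the 6418 genes at least 2-fold apart between the libraries at 5 CPM or more.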

Results

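The data comprised 1 single-cell library from the first leaf of the tea shoot, called the young leaf here, and 1 from the third leaf, called the mature leaf. The young-leaf library kept 8656 barcodes with 48016996 UMIs, a median of 3275 UMIs and 1803 genes per barcode. The mature-leaf library kept 7516 barcodes with 43891130 UMIs, a median of 3802 UMIs and 1776 genes per barcode. At least 1 UMI was found for 34614 genes in the young leaf and for 32250 in the mature leaf. The comparison addressed how leaf cells differ in their transcripts between a younger and an older leaf position of tea shoots. With 1 library per leaf, each value describes these libraries, and no difference could be set against a spread between replicates.

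Gene levels differed widely between the leaves, and 4 gene IDs were at opposite extremes. CSS0032332 stood at 416 CPM (95% Poisson interval 410 to 422) in the mature leaf and at 4.54 CPM (3.96 to 5.18) in the young leaf, a ratio of 91.6 (80.2 to 105). CSS0004766 stood at 192 CPM (188 to 196) in the mature leaf and 2.29 CPM (1.88 to 2.76) in the young leaf, a ratio of 83.9 (69.5 to 102). In the other direction, CSS0017322 stood at 450.5 CPM (444 to 457) in the young leaf and 0.570 CPM (0.369 to 0.841) in the mature leaf, where 25 UMIs were counted. It was 791 times higher in the young leaf (interval 536 to 1222). CSS0030446 had 2908 UMIs in the young leaf, or 60.6 CPM, and 2 UMIs in the mature leaf, a ratio of 1329 with a counting interval of 368 to 10980. A UMI of CSS0017322 was found in 45.9% of young-leaf barcodes and in 0.239% of mature-leaf barcodes, and one of CSS0004766 in 1.05% and 41.0%. The sizes of these ratios depended on the processing. CSS0032332 was 152 times higher in the mature leaf as a mean over barcodes, and CSS0004766 was 128 times higher by the median of ratios, which put CSS0017322 at 519 times higher in the young leaf. With every barcode thinned to one depth, CSS0030446 had 438 UMIs in the young leaf and 0 in the mature leaf, which gives only a bound, at least 134-fold higher when 3 counts stand for the 0. The files do not pair these IDs with gene names.

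Over all genes, 7886 reached 20 CPM in at least 1 library. Of these, 1060 were at least 2-fold higher in the mature leaf and 2161 at least 2-fold higher in the young leaf. At a ratio of 10, the counts were 78 and 228, and by TMM they were 136 and 143. The balance between the directions depended on the scaling. TMM moved every gene by 0.53 on the log2 scale towards the mature leaf and gave 2086 genes higher in the mature leaf and 1022 higher in the young leaf. The share of genes past the rule that were higher in the mature leaf was 32.9% by total counts, 67.1% by TMM and 71.5% by the median of ratios. Under all 3 scalings, 1060 genes were higher in the mature leaf and 909 in the young leaf. TMM and the median of ratios each moved all genes by a constant towards the mature leaf. These numbers are therefore the smallest count in each direction and not an agreement of independent results.

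**Figure D1:**
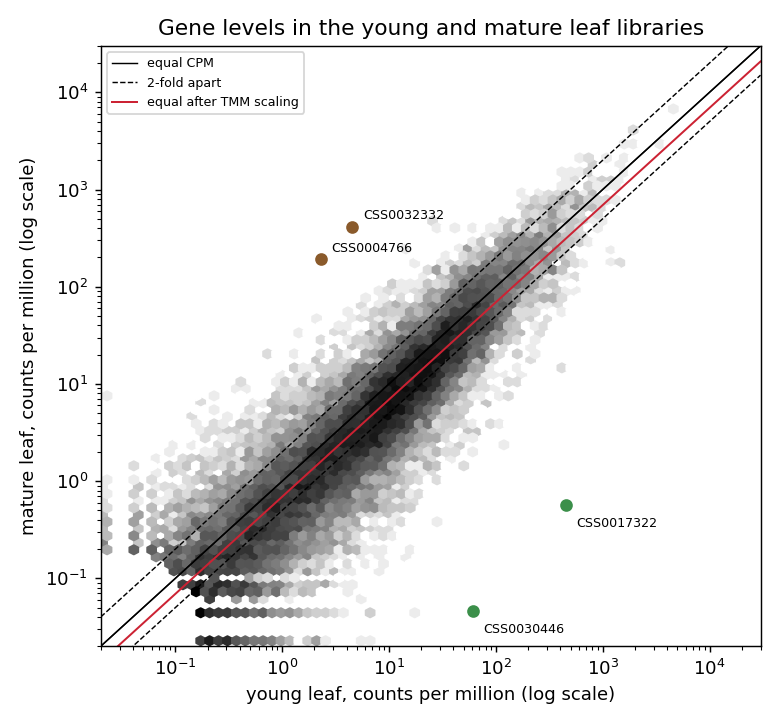
Level of each gene in the young leaf (x axis) and mature leaf (y axis), in CPM on log axes, as a density of genes with a UMI in both libraries and at least 10 UMIs in all. Black lines mark equal levels and 2-fold differences, the red line marks equal levels after TMM scaling, and the 4 named IDs lie far outside, with CSS0032332 at 416 CPM in the mature leaf and CSS0017322 at 450.5 CPM in the young leaf.

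Counts in the mature leaf were concentrated in fewer genes. The 1000 most abundant genes took 57.7% of the young-leaf UMIs and 64.7% of the mature-leaf UMIs, and the 100 most abundant took 24.6% and 28.4%. At least 20 CPM was reached by 7174 genes in the young leaf and 5827 in the mature leaf. With every barcode thinned to 1259 UMIs, the median barcode held 852 genes in the young leaf (quartiles 809 to 885, 7597 barcodes) and 801 in the mature leaf (765 to 827, 6962 barcodes). Thinning left out 1059 and 554 shallower barcodes. Before thinning the medians were 1803 and 1776 genes. The thinned median was lower in the mature leaf in 8 of the 8 compared clusters, by 31 to 73 genes.

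**Figure D2:**
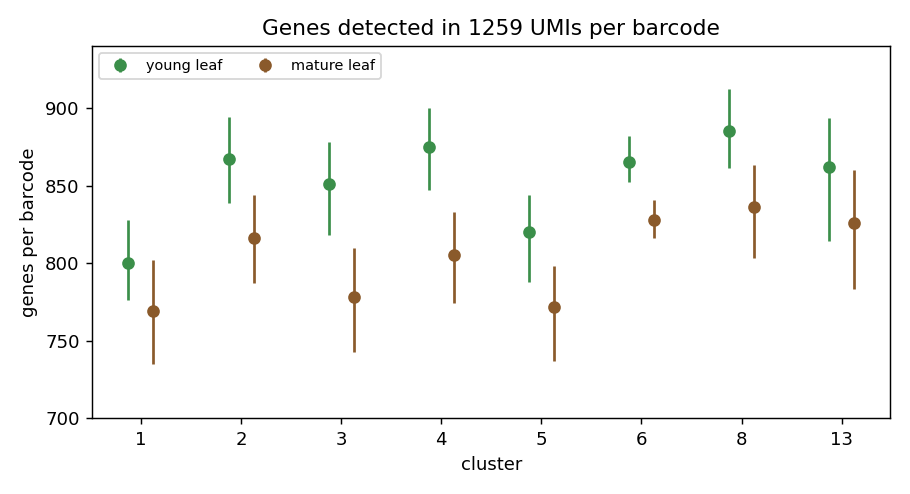
Genes detected per barcode (y axis, not starting at 0) after thinning to 1259 UMIs, for the 8 clusters with at least 100 barcodes in each library (x axis). Points are medians over barcodes and bars span the quartiles; the mature-leaf median lies below the young-leaf median in each of the 8 clusters, by 31 to 73 genes.

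Cells of both leaves fell into 15 joint clusters after integration, of which 8 held at least 100 barcodes of each library. These 8 held 77.6% of young-leaf and 78.8% of mature-leaf barcodes. Without integration almost no cluster was shared: 16 of 17 clusters had over 90% of their size-adjusted barcodes from 1 library. The leading gene ID of a cluster was at least 2-fold above the rest of its library in both leaves in 14 of the 15 clusters. The exception was CSS0046259 of cluster 12, at 5228 against 1365 CPM in the young leaf and 227 against 263 CPM in the mature leaf. In 6 clusters the leading ID was itself at least 2-fold apart between the leaves, such as CSS0029062 of cluster 2, at 114 CPM in the young leaf and 462 CPM in the mature leaf. In cluster 1, CSS0050075 stood at 400 CPM in the young leaf against 44.7 CPM in the other young-leaf barcodes, and at 344 against 14.9 CPM in the mature leaf. In cluster 4, CSS0015941 stood at 6260 against 1142 CPM in the young leaf and 7527 against 655 CPM in the mature leaf. In cluster 8, CSS0047756 stood at 350 against 11.3 CPM and at 190 against 3.89 CPM. In cluster 11, CSS0046578 stood at 1822 against 13.96 CPM and at 1552 against 10.1 CPM. In cluster 15, of 48 and 44 barcodes, CSS0031549 stood at 351 against 0.719 CPM and at 140.2 against 0.761 CPM. These IDs were picked for being high in their clusters, so the levels describe the clusters and are not a finding about them.

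For each of the 8 compared clusters, the profile relative to the rest of its own library was correlated across genes between the leaves. The correlation was a median of 0.71, from 0.52 in cluster 13 to 0.83 in cluster 4. Between different clusters the median was -0.01, with a highest value of 0.79. In 8 of 8 clusters the counterpart in the other leaf was the best match. The highest value between different clusters thus lay above the median of the matched ones. Genes are not independent replicates, and the clusters were drawn from these same genes. The integration also placed like barcodes of both libraries in one cluster, so a best match of counterparts was favored in advance.

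The share of cells in each cluster differed between the leaves by a total of 38.3% of barcodes (the summed absolute differences divided by 2, with 95% interval 37.0 to 39.7 for counting error). Cluster 1 held 18.3% of young-leaf barcodes (95% Clopper-Pearson interval 17.5 to 19.2) and 11.03% of mature-leaf barcodes (10.3 to 11.8). Its barcodes were deep, with medians of 9958 and 11773 UMIs, and it gave 33.2% of all young-leaf UMIs. Cluster 2 held 18.3% (17.5 to 19.2) and 9.09% (8.45 to 9.76), and cluster 6 held 8.72% (8.14 to 9.34) and 5.73% (5.22 to 6.28). Cluster 5 held 3.67% (3.29 to 4.09) and 17.1% (16.3 to 17.98), and cluster 3 held 9.95% (9.32 to 10.6) and 16.5% (15.7 to 17.4). Cluster 4 held 10.2% (9.54 to 10.8) and 10.8% (10.1 to 11.5), cluster 8 held 6.08% (5.58 to 6.60) and 6.51% (5.96 to 7.09), and cluster 13 held 2.32% (2.02 to 2.66) and 2.00% (1.69 to 2.34), intervals that overlap between the leaves. Of these 8 compared clusters, cluster 2 alone had a leading ID at least 2-fold apart between the leaves inside the cluster.

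These shares depended on the genes used for clustering. In a clustering that left out the genes at least 2-fold apart between the libraries, each of the 8 compared clusters was divided. Cluster B took 73.6% of cluster 1, together with 94.7% of cluster 14, and held 13.4% of young-leaf and 11.1% of mature-leaf barcodes, while cluster H took 10.8% of cluster 1 and held 6.22% and 5.71%, and cluster K took 12.7% of cluster 1 and 19.3% of cluster 2 and held 9.22% and 0.732%. Other parts of cluster 2 went to cluster I, with 34.96% of it and shares of 9.16% and 2.06%, and to cluster M, with 17.3% of it and shares of 1.35% and 5.601%. Cluster 5 went mostly to cluster C, which took 53.2% of it, drew 66.6% of its own barcodes from it and held 6.04% and 10.1%, and to cluster L, which took 38.0% of it and held 1.04% and 8.44%. Cluster 6 went to cluster E (45.5% of it) and cluster N (19.8% of it), each held mostly by 1 library. Cluster 3 was scattered. Cluster J took 34.8% of it, with 84.2% of its own barcodes from it, and held 2.59% and 8.58%. Cluster D took 21.5% of it but drew only 35.5% of its barcodes from it, and held 11.1% and 4.14%. Clusters 4 and 8 were both divided mainly between clusters A and G, so their likeness between the leaves could not be followed. Cluster A took 54.5% of cluster 4 and 45.9% of cluster 8, and held 21.1% and 12.2%. Cluster G took 25.8% of cluster 4 and 48.3% of cluster 8, and held 4.84% and 8.09%. Only 33.6% of A came from cluster 4, and 47.7% of G from cluster 8. Cluster 13 was scattered, with its largest part, 22.8%, in cluster M, so its likeness could not be followed either. Protoplast release can differ between leaves and cell types, and these shares are of captured barcodes.

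Cluster 7 was almost wholly of the mature leaf, with 4 young-leaf barcodes, or 0.0462% (0.0126 to 0.118), and 1164 mature-leaf barcodes, or 15.5% (14.7 to 16.3). Its leading ID, CSS0012232, itself differed within the cluster, at 28.6 CPM in those 4 barcodes and 795 CPM in the mature leaf. Those 4 barcodes held 104852 UMIs in all, so their value rests on few UMIs. In the other barcodes the ID stood at 11.5 CPM in the young leaf and 345 CPM in the mature leaf. It thus differed between the libraries outside the cluster too. The clustering without genes 2-fold apart still gave a cluster F with 10 young-leaf barcodes (0.116%) and 1139 mature-leaf barcodes (15.2%). Of the barcodes of F, 88.9% came from cluster 7. Leaving out those genes did not lower the difference between the leaves, which was 46.6% of barcodes in total. In that clustering, too, 4 clusters had over 90% of their size-adjusted barcodes from 1 library, and they held 22.8% of young-leaf and 23.6% of mature-leaf barcodes, against 14.2% and 18.3% in the joint clustering. Besides F these were E with 13.3% and 0.958%, K with 9.22% and 0.732%, and N with 0.150% and 6.76%. In the joint clustering, clusters 9, 10 and 14 were also over 90% of 1 library, with 9.08% and 0.732%, 4.94% and 0.239%, and 0.127% and 1.85% of barcodes. The genes that set these 3 clusters apart can include genes that differ between the libraries, so their sizes are given as values and no difference is drawn from them.

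**Figure D3:**
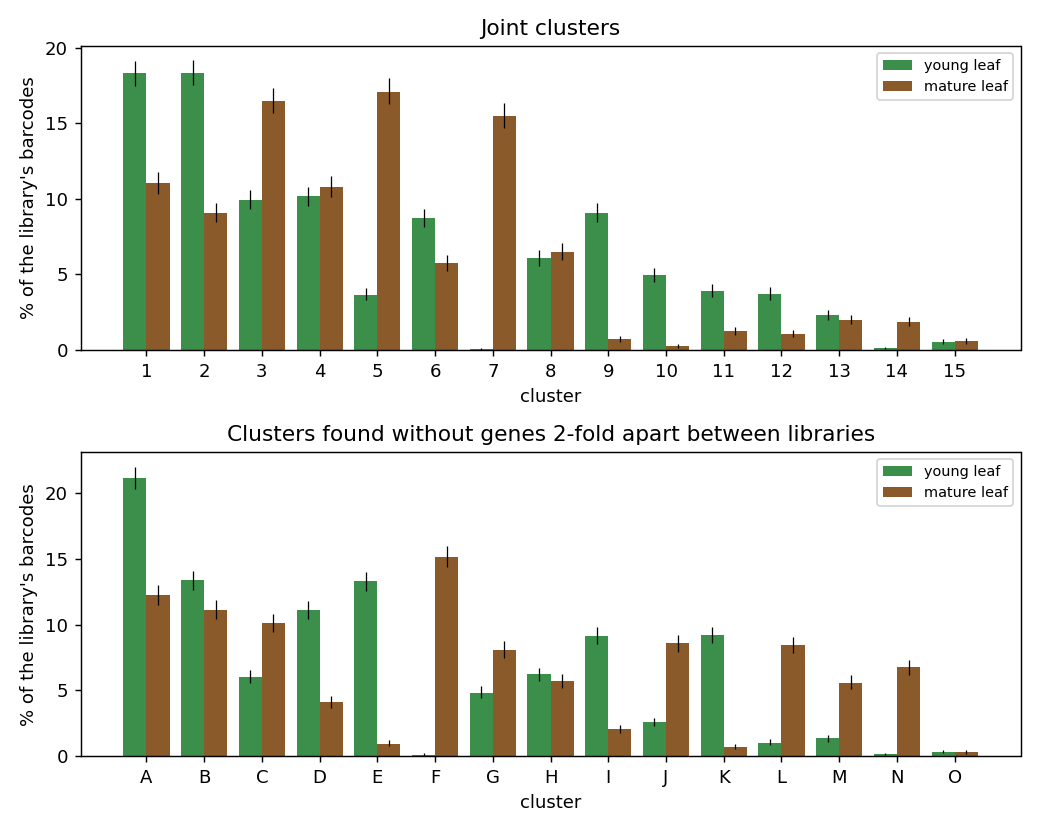
Share of each library's kept barcodes per cluster, in percent, with 95% Clopper-Pearson intervals for counting error as error bars, for the 15 joint clusters (top) and for the 15 clusters A to O found without genes 2-fold apart between the libraries (bottom). Cluster 7 and its counterpart F hold 15.5% and 15.2% of mature-leaf barcodes and under 1% of young-leaf barcodes.

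Gene levels also differed between the leaves inside clusters. The number of genes at least 2-fold apart in the 8 compared clusters had a median of 2607, from 1746 in cluster 1 to 3597 in cluster 3. In cluster 1, 632 genes were higher in the mature leaf and 1114 in the young leaf. In cluster 3 the numbers were 1195 and 2402. By TMM the direction of this balance turned, to 1019 and 721 in cluster 1 and 2341 and 1046 in cluster 3. In small clusters 20 CPM is few UMIs, 12.1 in the smaller library of cluster 13 and 197 in that of cluster 1. Part of the counts there can be sampling noise, which was not measured. In all 8 clusters, 129 genes were higher in the mature leaf and 139 in the young leaf, and 129 and 92 of them also passed by TMM. TMM moved levels towards the mature leaf in each cluster, so the 129 were bound to pass again.

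CSS0032332, CSS0004766 and CSS0017322 passed the rule in 8 of 8 clusters, and CSS0030446 in 3. CSS0032332 was highest in cluster 2 of the mature leaf, at 4043 CPM and in 87.7% of its barcodes. In the same cluster of the young leaf it stood at 2.13 CPM. Its highest young-leaf level among the 8 clusters was in cluster 13, at 50.8 CPM and in 4.48% of barcodes, against 305 CPM in the mature leaf. CSS0004766 was highest in cluster 8 of the mature leaf, at 1165 CPM, against 2.98 CPM in the young leaf. CSS0017322 was highest in cluster 2 of the young leaf, at 1421 CPM and in 86.8% of barcodes, against 4.61 CPM in the mature leaf. In clusters 3, 4, 5, 6 and 8 of the young leaf, with median depths of 1272 to 3233 UMIs against 3673 in cluster 2, it was found in 16.0% to 18.7% of barcodes. No cluster could be named as one that lacks the gene, so this like low share was not separated from free RNA. In the same 5 clusters of the mature leaf CSS0032332 was found in 13.3% to 24.6% of barcodes, which has the same limit. CSS0030446 was at 165 CPM in cluster 2 and 52.6 CPM in cluster 1 of the young leaf. In clusters 3, 4, 5, 6 and 8 it lay between 2.18 and 8.26 CPM.

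**Figure D4:**
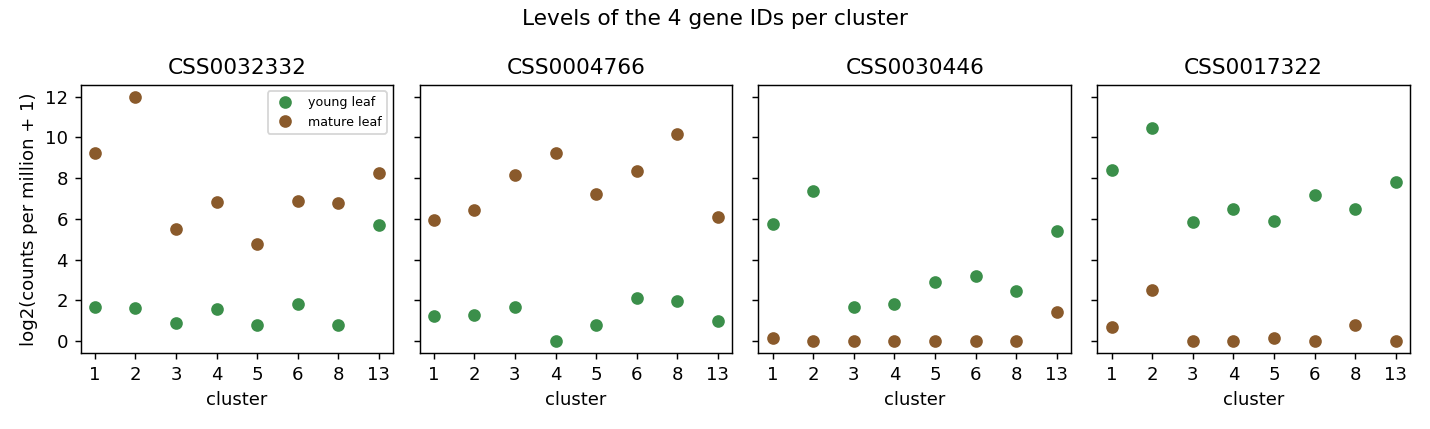
Level of the 4 named gene IDs, as log2 of CPM plus 1 (y axis), in the 8 compared clusters (x axis) of the young leaf (green) and mature leaf (brown), 1 library each. CSS0032332 reaches 4043 CPM in cluster 2 of the mature leaf and CSS0017322 reaches 1421 CPM in cluster 2 of the young leaf.

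The leaves were also compared with the 8 compared clusters at equal weight in both libraries, which leaves out the other 7 clusters. For the 3221 genes past the rule by total counts, the median absolute log2 ratio, with 1 CPM added, was 1.53 as measured in the whole libraries, 1.38 in the 8 clusters as they were mixed, and 1.13 at equal weight. The last value is 73.8% of the first and 81.5% of the second. The direction at equal weight was as measured for 99.7% of these genes. With 1 CPM added, 96.9% of them were at least 2-fold apart as measured, 82.96% in the 8 clusters as mixed and 61.3% at equal weight. The genes were picked for differing in the whole libraries, so some decrease can come from that choice where a gene's ratio varies between clusters.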

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

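Tests chosen after the result was seen were those of the genes that differ between the libraries and of the cluster mix behind the lower gene number. The others were fixed before their results were seen. In all patterns the leaf and the library are one and the same, so a biological difference between the leaves and a difference in preparing or sequencing the 2 libraries cannot be told apart.

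Of 7521 genes past the rule in at least 1 compared cluster, 93 went in opposite directions. They were at least 2-fold higher in the mature leaf in one cluster and at least 2-fold lower in another, under total-count and TMM scaling alike. Calls in small clusters can rest on few UMIs, and the difference between clusters was not tested.

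The libraries differed in many genes and separated almost completely without integration. With every barcode at one depth, 86.7% of the genes past the rule still passed it in the same direction. For most of these genes the difference thus did not rest on the greater weight of deep barcodes. Random thinning keeps the expected share of each gene within a barcode, so this test cannot argue against depth more widely. The clustering without integration was not repeated at one depth, so depth was not tested as a cause of the separation. The mix of clusters stays open as a part of the cause, since equal weights left 73.8% of the median difference, between the bounds of 50% and 80% set beforehand. That placing depends on the reference: relative to libraries without one-library clusters 81.0% was left, and relative to the compared clusters alone 81.5%. Free RNA of each library stays open. It should shrink the difference in deep barcodes, and for the genes apart in all 8 clusters barcodes at or above their cluster's median depth kept 86.2% (cluster 4) to 116% (cluster 3) of the median difference of the shallower ones, with clusters 4 and 5 under the 90% that would have argued against it.

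Clusters 7, 9, 10 and 14 were held almost wholly by 1 library. Shallow barcodes are argued against, as their median UMIs were at least 89.1% of the median of the library that held them. Doublets stay open. The median doublet score of these clusters exceeded at most 66.3% of the scores in that library, which was to argue against doublets below 75%, but the caller marked 0 barcodes and such scores can miss doublets of like cells. Cluster 14 had a median depth of 531% of its library's. A test added after the scores were seen asked for 20 genes with over 75% of their library's UMIs in the cluster, as single cells of a parent type should outnumber its doublets. It found 0 such genes in clusters 7 and 9, 5 in cluster 10 and 1 in cluster 14. Doublets were to give 0, so clusters 7 and 9 met that prediction, and clusters 10 and 14 met neither. The test decides nothing, because single cells that share their genes with other clusters can also give 0. Integration did not assemble them, since at least 93.3% of each sat in 1 cluster without it, but whether it failed to align them with cells of the other leaf stays open. Genes 2-fold apart by total counts are argued against for cluster 7, which kept a 78.9% overlap with a cluster found without them. The test does not reach further. By TMM, 2086 genes were 2-fold higher in the mature leaf at 20 CPM, against 1060 by total counts. Genes past a ratio of 2 only by TMM were not left out of that clustering, nor were smaller differences between the libraries. For clusters 9, 10 and 14 the overlap was at most 21.1%, which lay on the side of the bounds set for such genes as the cause. It cannot decide, because a cell type of 1 leaf would also have its own markers among the genes left out.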

How the results depend on the processing

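The alternatives were planned, except that leaving out high doublet scores, one-library clusters or uncompared clusters, all deposited barcodes as a source of gene counts, the clustering without genes 2-fold apart and thinning to 3000 UMIs were chosen after seeing the data. With 1 library per leaf, none of these settings stands for replicate error. The counts of 1060 genes higher in the mature leaf and 2161 in the young leaf stayed within 1.5 times under equal weight per barcode, thinning, all deposited barcodes, and without high doublet scores or one-library clusters, at 945 to 1061 and 1856 to 2186. They moved to 2086 and 1022 with TMM, 2282 and 909 with the median of ratios, 1600 and 4818 at a minimum of 5 CPM, and 2826 and 10334 at a minimum of 10 counts; the last 2 include more genes by construction and the low ones rest on few UMIs. The cluster shares differed by 97.9% without integration, 41.3% at resolution 0.3, 54.7% at resolution 1.0, 39.9% with 15 components, 43.9% without high doublet scores and 46.6% without the genes 2-fold apart, against 38.3%; the cause was not tested. The median number of genes 2-fold apart within clusters was 2523 with TMM and 1339 at a minimum of 50 CPM, where fewer genes can pass. The difference left at equal cluster mix was 68.9% at resolution 1.0, 72.4% at resolution 0.3, 81.0% relative to libraries without one-library clusters and 81.5% relative to the compared clusters alone. The median correlation of cluster profiles was 0.74 with 1 CPM added. Over all deposited barcodes the median depth was 2530 UMIs in the young leaf and 3568 in the mature leaf. At 3000 UMIs the median barcode had 7.38% fewer genes in the mature leaf, against 5.99%, a comparison itself chosen after seeing the data. For the 4 named IDs, chosen as the most extreme, 8 of 24 alternatives gave a ratio outside the counting interval and 1 gave only a bound: CSS0032332 ranged from 91.6 to 152 times, CSS0004766 from 79.4 to 128, CSS0017322 from 519 to 815, and CSS0030446 from 872 to 1385 apart from the thinned bound of at least 134. Not run were the gene list medians (no ID has a name), the removal of called doublets (0 were called) and the profile correlation without integration (0 clusters had 100 barcodes in both libraries). No paired analysis was possible because each leaf has 1 library.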

Other observations

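The lower number of genes per barcode in the mature leaf at equal depth was not planned as a comparison and is a hypothesis found in these data; the test of the cluster mix was chosen after the result was seen. The median fell short by 51 genes at 1259 UMIs and by 120 at 3000 UMIs. A few abundant genes may account for part of it: without the 100 most abundant genes the gap, thinned again to 1259 UMIs, was 29 genes, which is 56.9% of the first gap and between the bounds of 50% and 80% set before this test. That test also kept fewer barcodes, 6593 and 6171; with all genes these same barcodes had a gap of 49 genes, of which 59.2% was left. A different mix of clusters is argued against as the whole cause, because 8 of the 8 compared clusters had fewer genes in the mature leaf. Among the clusters not compared, 7, 10, 11, 12 and 15 also had fewer, and 9 and 14 went the other way. Cluster 9 had medians of 814 genes in the young leaf and 819.5 in 50 mature-leaf barcodes. Cluster 14 had 769 in 11 young-leaf barcodes and 772 in the mature leaf. A narrower set of active genes in cells of the older leaf remains an untested candidate explanation.

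Cluster 14, of 139 mature-leaf and 11 young-leaf barcodes, had the deepest mature-leaf barcodes, with a median of 20206 UMIs and 4517 genes. In the clustering without genes 2-fold apart between the libraries, 94.7% of its barcodes joined cluster B, of which 89.2% came from cluster 1, whose median in that leaf was 11773 UMIs.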
